A study of Homo sapiens with 16 samples.

How the data were processed

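The series holds RNA-seq of 4 breast cancer cell lines (MCF7 and lines labelled 231, ADR and T47D), each treated for 6 h with DMSO or 50 uM vinigrol. Each library was mapped to its group by its labels, which gave 8 groups of 2 libraries and left no library unassigned. Per the labels' protocols, the cells were bought from a cell bank, the MCF7 libraries were made with a 3' mRNA kit (QuantSeq) and the libraries of the other 3 lines with a dual-mode mRNA kit (Hieff NGS MaxUp II). A 3' kit reads mainly the transcript ends, so levels in MCF7 are not compared with those in the other 3 lines, which share a kit.

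For 231, ADR and T47D the deposited values were whole-number counts per gene, made with featureCounts 2.0.0 on exons grouped by gene, as pairs, with the Ensembl release 99 annotation of GRCh38, per the file headers. The headers show no strand option and no option for reads that map to several places, so reads of overlapping antisense partners cannot be told apart and near copies of a gene may lose or share reads. STAR, HISAT2 and featureCounts are named in the submitters' processing notes, without versions. For MCF7 the deposited values were estimated counts that need not be whole, with 991 to 1094 non-whole genes per library. They were rounded to whole numbers before any test. The annotation behind the MCF7 values was not given in the sources used here. No further normalization by the authors was recorded for either kind of deposited count.

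The MCF7 files list 41680 gene IDs, of which 41451 were given a symbol, and the other files 60676, of which 58575 were given one. Both kinds share 41269 IDs, and 0 rows named no gene. Coordinates are those of the featureCounts files (GRCh38, counted from 1). Total counts per library ran from 5550326 to 6641275 in MCF7 and from 12218619 to 17188953 in the other lines.

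Genes were kept with edgeR's filterByExpr (minimum count 10, by group), scaled with TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. MCF7 was fitted alone on 4 libraries (12559 genes, biological coefficient of variation 14.4%, 2 residual degrees of freedom). The 12 libraries of 231, ADR and T47D shared 1 fit with 6 group means (18145 genes, 7.6%, 6 residual degrees of freedom). All 16 libraries were fitted together over the shared IDs (18657 genes, 9%, 8 residual degrees of freedom) for the mean of the 4 effects and for MCF7 against the other lines. Differences between lines are interaction contrasts. SEs are on the log2 scale.

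Gene lists (28, fixed before the data were examined) covered stress responses (ATF4, ER chaperones and ERAD, heat shock, NRF2, metallothioneins), autophagy, lysosome, pro-apoptotic and anti-apoptotic genes, p53 targets, G1/S and G2/M genes, cholesterol and fatty acid synthesis, estrogen response, immediate early and MAPK feedback, NF-kB, interferon, hypoxia, glycolysis, nuclear respiratory chain, mitochondrial mRNAs, calcium handling, AHR targets, luminal and mesenchymal markers, immune cell markers and fibroblast and endothelial markers. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, two-sided, adjusted over the lists of a line, where at least 3 members were tested. An estimated correlation and fry were alternatives. Some genes stand in 2 lists, such as XBP1 in the ER and luminal lists.

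Genes were named by a rule fixed before the data were examined. It named 20 genes set in advance where they were tested (ATF4, DDIT3, TRIB3, CHAC1, ATF3, PHLDA1, HSPA5, DNAJB9, HMOX1, SQSTM1, CDKN1A, HMGCS1, LDLR, FOS, EGR1, CCND1, MYC, ESR1, ABCB1 and TNFRSF10B). Per line it took the 8 largest rises and 8 largest falls among called genes with a mean of at least 10 CPM in the higher group, both vinigrol libraries beyond both DMSO libraries and a symbol that is more than a clone name. It added up to 4 members of a list with the smallest adjusted p, the 10 genes per direction with the smallest adjusted p among those called alike in all 4 lines, and for each difference between lines the 4 genes with the smallest adjusted p among those with an absolute log2 difference of at least 1 and a mean of at least 10 CPM in the higher group. A gene with 0 counts in one group is given a lower bound against 3 counts per library, and a gene with 1 to 3 counts over a group the ratio of summed counts with an exact 95% interval from the binomial test.

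Overlaps of called genes were set against the product of the list sizes over the genes tested in both lines, with Fisher's exact test. The lines share no control libraries. Alternatives fixed before the data were examined were RLE size factors, library totals alone, DESeq2 1.42.0, limma voom, no count filter, at least 1 CPM in 2 libraries, a 2-fold threshold, a block for the replicate number, each line fitted alone, each line left out of the mean effect and each library left out in turn. A minimum mean of 1 CPM within the line, a normalization without mitochondrial genes and counts of list and family members with each library of a line left out were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

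The tests were run on simulated counts drawn from the real means and depths, with 200 genes changed by folds of 1.5, 2 and 4. In MCF7 (12276 genes) 6%, 49.3% and 78.8% of these were called, and 3.3% of calls were false. In 231 (17658 genes) the shares were 44.8%, 62.7% and 74.2%, with 6.9% false calls. For 231 minus ADR (17698 genes) they were 19.4%, 46.3% and 74.2%, with 7.9% false calls, and for the mean effect (18102 genes) 53.7%, 47.8% and 69.7%, with 3.4%. Of 28 simulated lists in 231, the 5 raised 1.5-fold were called and 0 others. Genes were drawn independently, so false calls of correlated lists were not tested.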

Results

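The data were RNA-seq counts from 4 human breast cancer cell lines that had been treated for 6 h with 50 uM vinigrol, a diterpenoid first isolated from a fungus, or with the solvent DMSO. MCF7 and T47D are established luminal breast cancer lines. The other 2 lines carry only the labels 231 and ADR, which are used here as names. Each of the 8 groups held 2 libraries, 16 in all. Total counts ran from 5550326 to 6641275 per library in MCF7 and from 12218619 to 17188953 in 231, ADR and T47D. Levels are CPM with TMM scaling, as mean ± SD of 2 libraries. Changes are log2 fold changes ± SE of vinigrol against DMSO, with adjusted p-values from edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of libraries agreed within sampling noise, since the chi-square per degree of freedom of a pair ran from 1.54 in 231 with vinigrol to 22.1 in ADR with DMSO.

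In the 3 lines made with the same library kit, the estrogen receptor gene ESR1 stood at 349 ± 5.69 CPM in T47D with DMSO, against 0.39 ± 0.00727 CPM in 231 and 0.402 ± 0.488 CPM in ADR. In MCF7 it was at 89.4 ± 0.912 CPM, which another kit measured and which is not set against the other lines. ABCB1, which encodes a drug efflux pump, was at 2240 ± 309 CPM in ADR with DMSO, 3.96 ± 2.88 CPM in 231 and 0.129 ± 0.101 CPM in T47D. The share of counts on the 13 mitochondrial mRNAs was lower with vinigrol in all 8 treated libraries than in the DMSO libraries of the same line. It was 20.31% and 19.1% in the T47D libraries with DMSO against 14.01% and 13.06% with vinigrol, and 6.38% and 6.2% against 3.84% and 4.14% in MCF7. In ADR the shares were 10.17% and 12.17% against 8.47% and 9.03%, and in 231 they were 10.81% and 10.56% against 9.78% and 9.75%. The share on mitochondrial rRNA was higher with vinigrol in the same 8 comparisons, at 0.66% and 0.71% against 1.38% and 1.31% in T47D and 1.39% and 1.73% against 2.31% and 2.34% in MCF7. It was 0.51% and 0.66% against 0.74% and 0.73% in ADR, and 0.98% and 0.93% against 1.05% and 1.05% in 231.

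The first question was which genes vinigrol changed in MCF7, the line named in the series title. In MCF7 most tested members of the immediate early and MAPK feedback, NF-kB, ATF4 integrated stress response and endoplasmic reticulum (ER) chaperone lists rose, while 10 of 27 G1/S genes and ESR1 fell. Of the 9 lists called in MCF7, 0 kept their call with an estimated correlation, a test that rests on 2 residual degrees of freedom here. EGR1, an immediate early transcription factor (ENSG00000120738, GRCh38 chromosome 5, 138465479 to 138469303), went from 12.4 ± 3.89 to 1060 ± 126 CPM, an 85-fold rise (log2 6.41 ± 0.22, adjusted p = 1.7e-09). AREG, which encodes the EGF receptor ligand amphiregulin (ENSG00000109321, chromosome 4, 74445136 to 74455005), rose 60.9-fold to 1930 ± 14.2 CPM. ESR1 fell 2.29-fold to 39.1 ± 1.23 CPM (log2 -1.19 ± 0.16, adjusted p = 0.0002).

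Compared with DMSO, 2456 of 12559 genes tested in MCF7 passed an adjusted p of 0.05 (1442 higher, 1014 lower), and 1391 of them differed at least 2-fold (812 higher, 579 lower). Scaling by library totals alone gave 1195 higher and 1413 lower, and moved the median of all genes from 0.00 to -0.10. Leaving out MCF7_DMSO replicate 1 left 1594 calls.

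The 8 largest rises in MCF7 included 3 matrix metalloproteinase genes that lie together on chromosome 11. Of the 9 genes of this family tested 5 rose and 2 fell, a count made after the data were seen. MMP10 (102770502 to 102780628) had 0 counts in both DMSO libraries and 117 ± 14.3 CPM with vinigrol, at least 258-fold higher when 3 counts per DMSO library are allowed. MMP1 (102789919 to 102798160) had 2 counts over the DMSO libraries and 1289 with vinigrol, a ratio of 782 with an exact 95% counting interval of 216 to 6460. MMP13 (102942995 to 102955732) had 1 count against 648, a ratio of 786 with an interval of 141 to 31100. Such intervals and floors cover counting error only. IGFL1, a secreted growth factor-like protein gene, went from 0 counts to 19.9 ± 3.28 CPM, at least 43.7-fold higher. TNFRSF11B, which encodes osteoprotegerin, rose 603-fold to 241 ± 54.1 CPM. CAPN8, KCNF1 and EGR2 each had 1 count over the DMSO libraries and reached 33.3 ± 7.21, 32.8 ± 14.3 and 31.8 ± 14.5 CPM. The 8 largest falls were those of CUTA, AFAP1L2, SOX18, PRR15L, NFATC4, TRERF1, TRGJP and SEMA3F. CUTA fell 14-fold, from 19.6 ± 0.254 to 1.37 ± 0.36 CPM, and the semaphorin gene SEMA3F fell 8.15-fold, from 113 ± 9.57 to 13.8 ± 2.43 CPM. TRGJP, a T cell receptor gamma joining segment of 10.8 ± 9.3 CPM with DMSO, varied most between its libraries and had an adjusted p of 0.054 with limma voom and 0.14 without MCF7_DMSO replicate 2.

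Of the immediate early and MAPK feedback list, 21 of 24 tested members rose in MCF7 and none fell (22 rose when adjusted over the list alone), with a median of 2.56 (camera adjusted p = 4.3e-46, adjusted p = 0.24 with an estimated correlation). DUSP4, a MAP kinase phosphatase gene, reached 176 ± 5.19 CPM from 3.39 ± 1.91, and PHLDA1 reached 88.1 ± 5.52 CPM from 1.8 ± 0.753. JUNB rose 8.41-fold to 917 ± 113 CPM. Among NF-kB and inflammatory genes 11 of 16 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 2.12 (camera adjusted p = 2.8e-18, adjusted p = 0.24 with an estimated correlation). RELB, an NF-kB subunit gene, rose 66.6-fold to 148 ± 9.53 CPM and the cytokine gene LIF 70.4-fold to 108 ± 18.3 CPM.

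In the ATF4 integrated stress response list 32 of 39 members rose and 1 fell in MCF7 (33 and 1 adjusted over the list alone), with a median of 1.33 (camera adjusted p = 1.7e-35, adjusted p = 0.5 with an estimated correlation). CHAC1, a glutathione-degrading enzyme gene, went from 1.07 ± 0.276 to 61.9 ± 13.8 CPM, the cystine transporter gene SLC7A11 from 12 ± 1.55 to 246 ± 22.4 CPM and GDF15 from 30.5 ± 1.12 to 743 ± 74.4 CPM. ER chaperones and ERAD genes rose in 22 of 37 cases with none lower (27 adjusted over the list alone), at a median of 0.67 (camera adjusted p = 3.2e-10, adjusted p = 0.24 with an estimated correlation). DNAJB9 rose 4.8-fold. The autophagy list had 10 of 27 members higher and none lower (the same adjusted over the list alone), at a median of 0.19 (camera adjusted p = 0.02, adjusted p = 0.62 with an estimated correlation). SQSTM1, the autophagy receptor p62, rose 2.62-fold to 783 ± 285 CPM.

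Cholesterol synthesis genes were higher in 9 of 24 cases and lower in 1 (11 and 2 adjusted over the list alone), at a median of 0.41 (camera adjusted p = 0.017, adjusted p = 0.66 with an estimated correlation). HMGCS1 rose 2.73-fold. The call of the list was lost without MCF7_DMSO replicate 2 (adjusted p = 0.062) or without MCF7_vinigrol replicate 1 (adjusted p = 0.17). Of 8 interferon response genes tested 3 rose and none fell (3 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 0.049, adjusted p = 0.66 with an estimated correlation). This call was lost without MCF7_DMSO replicate 1 (adjusted p = 0.12) and without MCF7_vinigrol replicate 2 (adjusted p = 0.14), and STAT1 had risen from 44.8 ± 4.1 to 95.5 ± 3.21 CPM. G1/S genes fell in 10 of 27 cases with none higher (12 adjusted over the list alone), at a median of -0.42 (camera adjusted p = 0.0004, adjusted p = 0.66 with an estimated correlation). Without MCF7_DMSO replicate 1, 4 of them fell. E2F1 fell 2.26-fold and UNG, a base excision repair gene, 2.39-fold. Mitochondrial mRNAs fell in 6 of 13 cases with none higher (6 adjusted over the list alone), at a median of -0.39 (camera adjusted p = 0.018, adjusted p = 0.5 with an estimated correlation). Without MCF7_DMSO replicate 2 or MCF7_vinigrol replicate 1 the adjusted p was 0.07 and 0.079.

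The other 17 lists tested in MCF7 did not pass, at camera adjusted p-values from 0.09 to 0.78. Higher and lower members numbered 3 and 0 of 18 for heat shock, 7 and 0 of 22 for NRF2, 0 and 1 of 5 for metallothioneins, 4 and 1 of 21 for lysosome. They were 6 and 1 of 12 for pro-apoptotic genes, 2 and 1 of 8 for anti-apoptotic genes and 5 and 3 of 21 for p53 targets. For G2/M genes they were 0 and 1 of 26, for fatty acid synthesis 1 and 1 of 13 and for estrogen response 1 and 4 of 20. Hypoxia genes had 3 and 1 of 15, glycolysis genes 2 and 1 of 16 and nuclear respiratory chain genes 0 and 1 of 31. For calcium handling they were 4 and 3 of 22, for AHR targets 3 and 1 of 6, for luminal and epithelial markers 4 and 3 of 19 and for mesenchymal and basal markers 3 and 0 of 11. HMOX1 of the NRF2 list rose 6.35-fold and MCL1 of the anti-apoptotic list rose to 3070 ± 25.5 CPM from 1000 ± 22.4, while BCL2 fell from 57.3 ± 2.69 to 24.2 ± 0.653 CPM. The median was below 0 and the mean above 0 for lysosome, p53 targets, glycolysis and calcium handling, whose camera direction was up. Adjusted over the list alone, the higher and lower counts became 6 and 0 for heat shock, 7 and 2 for pro-apoptotic genes, 5 and 4 for p53 targets, 0 and 0 for G2/M genes and the nuclear respiratory chain, 3 and 2 for fatty acid synthesis and 3 and 4 for estrogen response, with the other counts the same. Adjusted over all genes, 1 library left out moved the counts of heat shock (9 and 1 without MCF7_vinigrol replicate 1) and fatty acid synthesis (4 and 1 without MCF7_vinigrol replicate 2) by over 1.5 times and at least 3 members. Immune cell markers and fibroblast and endothelial markers had too few tested genes in MCF7 for a list test.

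**Figure D1:**
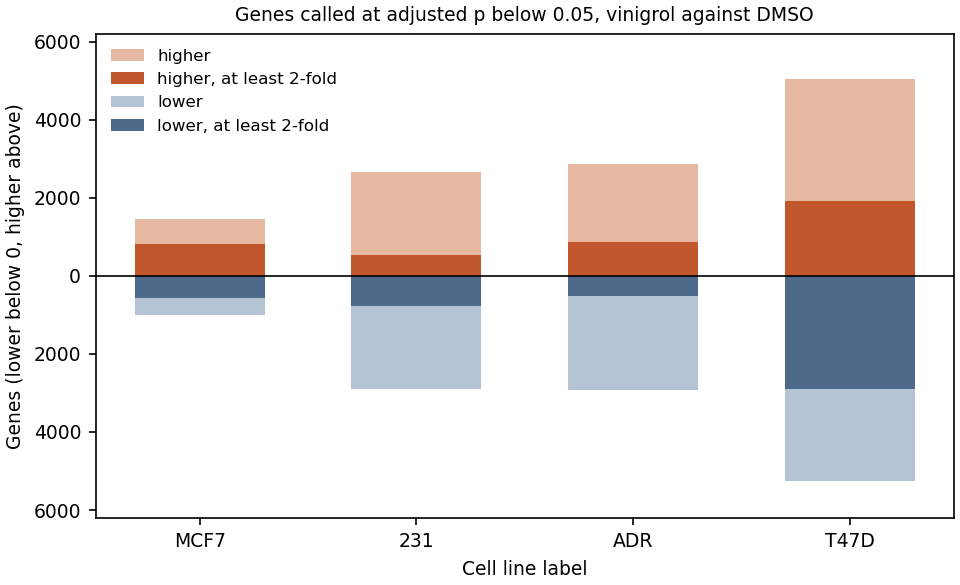
Genes called in each cell line at an adjusted p below 0.05, vinigrol against DMSO, with higher genes above 0 and lower genes below 0 on the vertical axis, and the part that differed at least 2-fold in the darker colour. T47D had 10290 calls, 4797 of them at least 2-fold, against 5557 in 231 and 5784 in ADR in the same fit, and MCF7, fitted alone at a lower depth, had 2456.

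In the line labelled 231, most tested members of the immediate early and MAPK feedback, NF-kB and ER chaperone lists rose, and most G1/S and G2/M genes, interferon response genes and luminal markers fell. Of the 13 lists called in 231, 3 kept their call with an estimated correlation, namely immediate early and MAPK feedback, NF-kB and G1/S genes. PTGS2, the inducible cyclooxygenase gene (ENSG00000073756, chromosome 1, 186671791 to 186680423), rose 10.2-fold from 23.4 ± 1.9 to 239 ± 12.5 CPM (log2 3.35 ± 0.11, adjusted p = 4.9e-16). EGR1 rose 9.82-fold to 202 ± 11.2 CPM and MYC 2.65-fold to 242 ± 3 CPM. The stem cell marker gene LGR5 (ENSG00000139292, chromosome 12, 71439798 to 71586310) fell 14.3-fold, from 11.7 ± 0.825 to 0.821 ± 0.216 CPM (log2 -3.84 ± 0.31, adjusted p = 2.5e-09).

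In total, 5557 of 18145 genes tested in 231 were called (2659 higher, 2898 lower), of which 1311 differed at least 2-fold (537 higher, 774 lower). With library totals alone 1927 were higher and 3806 lower, and the median of all genes moved from -0.02 to -0.13. Higher genes were the more numerous with DESeq2 (2409 and 2237) and with 231 fitted alone (4042 and 3851). Without 231_vinigrol replicate 2 the count was 3589. Besides PTGS2 and EGR1, the 8 largest rises were those of LINC02392, a noncoding RNA (14.1-fold, to 11.2 ± 1.32 CPM), and the genes of the cytokine TNFSF15 (12.5-fold), the BCL2 relative BCL2A1 (9.15-fold), INHBA (8.85-fold), PINLYP (8.51-fold) and stanniocalcin STC1, at 856 ± 20.8 against 102 ± 7.67 CPM. After LGR5 the largest falls were ERBB3 (6.69-fold), P2RY6 (6.59-fold), LFNG (6.52-fold), CAVIN2 (6.19-fold), SMAD6 (5.23-fold), PIK3C2B (5.15-fold) and MAP3K8 (4.97-fold). ABCB1 was at 3.96 ± 2.88 CPM with DMSO and 0.174 ± 0.132 CPM with vinigrol (log2 -4.42 ± 0.59, adjusted p = 2.7e-06). The change was -3.33 without 231_DMSO replicate 1 and -5.51 without 231_vinigrol replicate 2. The DMSO libraries of 231 stood at 5.998 and 1.926 CPM of ABCB1, against a mean of 2240 CPM in ADR. The median share of ADR-specific transcripts in them was 0.151% and 0 (upper quartiles 0.276% and 0.105%).

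In 231 the immediate early and MAPK feedback list had 20 of 26 members higher and none lower (21 and 1 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 1.5e-17, adjusted p = 0.037 with an estimated correlation). DUSP5 rose from 64.8 ± 2.56 to 377 ± 4.53 CPM and FOSL1 from 445 ± 1.58 to 1500 ± 18.5 CPM. NF-kB and inflammatory genes were higher in 15 of 22 cases and lower in 1 (the same adjusted over the list alone), at a median of 1.22 (camera adjusted p = 6e-15, adjusted p = 0.037 with an estimated correlation). ICAM1 rose from 118 ± 5.04 to 664 ± 32 CPM, IL1B from 16.4 ± 0.71 to 110 ± 1.47 CPM and IL6 from 30.4 ± 0.583 to 117 ± 6.76 CPM. G1/S genes fell in 25 of 27 cases and none rose (27 adjusted over the list alone), with a median of -0.76 (camera adjusted p = 7.5e-17, adjusted p = 0.037 with an estimated correlation). UHRF1 fell from 172 ± 0.859 to 72.9 ± 6.21 CPM and the helicase gene MCM6 from 68.1 ± 1.09 to 30.1 ± 1.1 CPM. G2/M genes fell in 23 of 26 cases and none rose (23 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.3e-16, adjusted p = 0.057 with an estimated correlation). Topoisomerase gene TOP2A fell from 1040 ± 43.2 to 480 ± 11.9 CPM and the kinesin gene KIF20A from 184 ± 8.03 to 56.6 ± 4.01 CPM.

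ATF4 list members rose in 22 of 42 cases and fell in 3 in 231 (23 and 3 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 1.3e-07, adjusted p = 0.17 with an estimated correlation). TRIB3 rose 2.71-fold. ER chaperones and ERAD genes rose in 27 of 38 cases and fell in 1 (the same adjusted over the list alone), at a median of 0.50 (camera adjusted p = 4.4e-14, adjusted p = 0.058 with an estimated correlation). DNAJB9 rose 4.93-fold and HSPA5, the main ER chaperone, 1.84-fold to 1320 ± 2.56 CPM. Heat shock genes rose in 8 of 19 cases and fell in 1 (11 and 1 adjusted over the list alone), at a median of 0.27 (camera adjusted p = 0.0011, adjusted p = 0.49 with an estimated correlation). The members that rose numbered 5 without 231_DMSO replicate 2. Autophagy genes rose in 13 of 27 cases with none lower (13 adjusted over the list alone), at a median of 0.27 (camera adjusted p = 5.9e-05, adjusted p = 0.11 with an estimated correlation). Pro-apoptotic genes rose in 5 of 13 cases with none lower (6 and 1 adjusted over the list alone), at a median of 0.34 (camera adjusted p = 0.04, adjusted p = 0.15 with an estimated correlation). The call was lost without 231_DMSO replicate 1 (adjusted p = 0.064). Anti-apoptotic genes rose in 7 of 8 cases and fell in 1 (the same adjusted over the list alone), at a median of 0.35 (camera adjusted p = 0.00037, adjusted p = 0.057 with an estimated correlation). BIRC3 rose from 190 ± 9.18 to 460 ± 11.8 CPM, and 4 of the 8 rose without 231_DMSO replicate 1, 231_DMSO replicate 2 or 231_vinigrol replicate 2.

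Hypoxia genes rose in 8 of 16 cases and fell in 3 in 231 (9 and 3 adjusted over the list alone), at a median of 0.24 (camera adjusted p = 0.026, adjusted p = 0.24 with an estimated correlation). NDRG1 rose from 247 ± 0.086 to 553 ± 7.22 CPM. With 1 library of 231 left out, the hypoxia genes that rose numbered 5 without 231_vinigrol replicate 2 and 4 without any of the other 3. Interferon response genes fell in 11 of 20 cases and none rose (11 adjusted over the list alone), at a median of -0.60 (camera adjusted p = 3.4e-05, adjusted p = 0.24 with an estimated correlation). IFIT1 fell from 35.1 ± 0.608 to 10.4 ± 1.07 CPM and IFIT3 from 97.4 ± 1.94 to 52.2 ± 2.96 CPM. Luminal and epithelial markers fell in 10 of 19 cases and rose in 1 (the same adjusted over the list alone), at a median of -0.47 (camera adjusted p = 0.011, adjusted p = 0.15 with an estimated correlation). Those that fell numbered 6 without 231_DMSO replicate 1 or 2, and 5 without 231_vinigrol replicate 1 or 2. The member that rose was XBP1, also a gene of the ER list, while the transcription factor gene SPDEF fell from 120 ± 2.26 to 30.1 ± 0.038 CPM and the keratin gene KRT19 from 326 ± 16.2 to 172 ± 0.195 CPM.

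The remaining 15 lists in 231 had camera adjusted p-values from 0.075 to 0.68. Higher and lower members numbered 3 and 5 of 23 for NRF2, 1 and 0 of 7 for metallothioneins, 3 and 3 of 23 for lysosome and 8 and 7 of 20 for p53 targets. Lipid and hormone lists had 7 and 7 of 25 for cholesterol synthesis, 3 and 7 of 14 for fatty acid synthesis and 4 and 4 of 20 for estrogen response. They were 2 and 0 of 16 for glycolysis, 0 and 2 of 31 for the nuclear respiratory chain, 2 and 0 of 13 for mitochondrial mRNAs, 5 and 5 of 23 for calcium handling and 1 and 3 of 7 for AHR targets. Mesenchymal and basal markers had 4 and 2 of 16, immune cell markers 0 and 1 of 6 and fibroblast and endothelial markers 1 and 1 of 6. Median and mean had opposite signs for metallothioneins, p53 targets, glycolysis, AHR targets and immune cell markers. Adjusted over the list alone, the higher and lower counts became 8 and 8 for p53 targets, 8 and 7 for cholesterol synthesis and 0 and 1 for the nuclear respiratory chain, with the other counts the same. For counts adjusted over all genes, moves of over 1.5 times and at least 3 members came without 231_vinigrol replicate 1 for NRF2 (1 and 1), lysosome (2 and 0), estrogen response and calcium handling (both 4 and 1). Without 231_vinigrol replicate 2 they came for p53 targets (5 and 4), cholesterol synthesis (5 and 2), fatty acid synthesis (3 and 4) and calcium handling (4 and 1). They were seen for NRF2 (1 and 2) and fatty acid synthesis (3 and 4) without 231_DMSO replicate 1, and for NRF2 (1 and 2), p53 targets (6 and 4), estrogen response and calcium handling (both 4 and 1) without 231_DMSO replicate 2. Within the p53 list CDKN1A, the gene of the cell cycle inhibitor p21, rose 3.21-fold to 807 ± 0.749 CPM, while the DNA repair gene DDB2 fell from 24 ± 1.08 to 7.8 ± 1.73 CPM.

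In ADR 21 of 22 NF-kB and inflammatory genes rose. CXCL8, the interleukin 8 gene (ENSG00000169429, chromosome 4, 73740541 to 73743716), went from 1.17 ± 1.41 to 315 ± 31.6 CPM, a 299-fold rise (log2 8.22 ± 0.27, adjusted p = 8e-18). The log2 change of CXCL8 was 7.17 without ADR_DMSO replicate 1 and 10.78 without ADR_DMSO replicate 2. The apoptosis inhibitor gene BIRC3 went from 3.44 ± 0.838 to 238 ± 29.6 CPM, and CDKN1A rose 11.9-fold to 333 ± 18.2 CPM. Of the G1/S genes 20 of 27 fell. The DMSO libraries of ADR, the pair with the highest chi-square per degree of freedom (22.1, a measure that grows with depth), had 5.04% and 6.38% of counts on ribosomal protein genes against 4.57% and 4.85% with vinigrol. ABCB1 itself was 1.42-fold higher, at 3190 ± 56.7 CPM (log2 0.51 ± 0.15, adjusted p = 0.0096). The ABCB1 call was lost with DESeq2 (adjusted p = 0.57) and without ADR_vinigrol replicate 1 (adjusted p = 0.055).

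Compared with DMSO, 5784 of 18145 genes were called in ADR (2863 higher, 2921 lower), with 868 higher and 520 lower at least 2-fold. Higher and lower genes were close in number, and higher genes were the more numerous under several alternatives, among them DESeq2 (2531 and 2252) and ADR fitted alone (2320 and 1714). IRAK2, a kinase gene of interleukin 1 signalling (ENSG00000134070, chromosome 3, 10164919 to 10243745), had 0 counts in both DMSO libraries and 14.3 ± 1.16 CPM with vinigrol, at least 72.2-fold higher. BCL2A1 had 3 counts over the DMSO libraries and 856 with vinigrol, a ratio of 319 with an exact 95% counting interval of 109 to 1550. The other large rises were those of CXCL1 to 116 ± 3.22 CPM, CXCL3 to 35.8 ± 1.8, ESM1 to 77.5 ± 6.45, G0S2 to 220 ± 7.33 and IL1B to 131 ± 14.1 CPM. CXCL1 and CXCL3 have near copies with which they may share reads. The largest falls were those of CAVIN2 (11.8-fold), TXNIP (8.09-fold), KRT80 (5.95-fold), SYT16 (5.89-fold), LINP1 (5.82-fold), SCN2B (4.88-fold), TMEM139 (4.68-fold) and the kinase gene PLK2, which fell from 769 ± 116 to 169 ± 13.4 CPM.

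In the NF-kB and inflammatory list 21 of 22 members rose in ADR and none fell (21 adjusted over the list alone), with a median of 4.35 (camera adjusted p = 1.1e-50, adjusted p = 0.0053 with an estimated correlation). ICAM1 rose from 85.2 ± 4.24 to 1830 ± 28.6 CPM and TNFAIP3, an inhibitor of NF-kB signalling, from 5.34 ± 0.376 to 261 ± 4.83 CPM. Immediate early and MAPK feedback genes rose in 25 of 26 cases and fell in 1 (the same adjusted over the list alone), at a median of 1.27 (camera adjusted p = 1.7e-27, adjusted p = 0.0053 with an estimated correlation). DUSP6 rose from 8.78 ± 0.158 to 127 ± 5.46 CPM and FOSL1 from 296 ± 42.4 to 2300 ± 79.1 CPM. Anti-apoptotic genes rose in 6 of 8 cases and fell in 1 (the same adjusted over the list alone), at a median of 1.13 (camera adjusted p = 9.9e-07, adjusted p = 0.021 with an estimated correlation). Pro-apoptotic genes rose in 7 of 13 cases with none lower (7 adjusted over the list alone), at a median of 0.85 (camera adjusted p = 4.4e-05, adjusted p = 0.025 with an estimated correlation). The death receptor gene TNFRSF10B rose 3.29-fold to 139 ± 5.44 CPM and PMAIP1 rose to 41.4 ± 1.22 CPM from 14.8 ± 3.09.

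ATF4 list members rose in 34 of 42 cases with none lower in ADR (34 adjusted over the list alone), at a median of 0.80 (camera adjusted p = 5.1e-22, adjusted p = 0.04 with an estimated correlation). With GDF15, at 0 counts under DMSO, set to its bound the median was 0.74. SESN2 rose from 9.69 ± 0.244 to 65.5 ± 1.54 CPM and DDIT4 from 1.67 ± 0.18 to 18.9 ± 1.93 CPM, whereas ATF3 was at 4.66 ± 0.0641 and 4.34 ± 0.267 CPM (adjusted p = 0.71). ER chaperones and ERAD genes rose in 23 of 38 cases with none lower (24 and 1 adjusted over the list alone), at a median of 0.35 (camera adjusted p = 1.9e-09, adjusted p = 0.13 with an estimated correlation). The ER stress sensor gene ERN1 rose from 21.4 ± 8.55 to 121 ± 2.28 CPM. Autophagy genes rose in 10 of 27 cases and fell in 1 (12 and 2 adjusted over the list alone), at a median of 0.23 (camera adjusted p = 0.005, adjusted p = 0.2 with an estimated correlation). Without ADR_vinigrol replicate 1, 6 rose. Mesenchymal and basal markers rose in 10 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone), at a median of 0.34 (camera adjusted p = 0.00037, adjusted p = 0.15 with an estimated correlation). LOX rose from 36.6 ± 3.65 to 174 ± 2.17 CPM. Estrogen response genes rose in 6 of 20 cases with none lower (6 adjusted over the list alone), at a median of 0.11 (camera adjusted p = 0.042, adjusted p = 0.16 with an estimated correlation). It was lost without ADR_DMSO replicate 2 (adjusted p = 0.059). Members that rose included AREG, an EGF receptor ligand, and NRIP1, a nuclear receptor corepressor, while ESR1 stayed under 1 CPM.

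G1/S genes fell in 20 of 27 cases with none higher in ADR (22 adjusted over the list alone), at a median of -0.56 (camera adjusted p = 9.4e-11, adjusted p = 0.04 with an estimated correlation). MCM3 fell 1.93-fold to 106 ± 3.54 CPM. G2/M genes fell in 12 of 26 cases and rose in 2 (14 and 3 adjusted over the list alone), at a median of -0.31 (camera adjusted p = 0.0033, adjusted p = 0.34 with an estimated correlation). CCNB2 fell from 88.6 ± 14.6 to 56.2 ± 4.19 CPM, while the kinetochore motor gene CENPE rose from 61.5 ± 6.21 to 114 ± 15.3 CPM. Cholesterol synthesis genes fell in 11 of 25 cases and rose in 3 (12 and 4 adjusted over the list alone), at a median of -0.27 (camera adjusted p = 0.012, adjusted p = 0.15 with an estimated correlation). IDI1 fell from 159 ± 3.69 to 93 ± 4.88 CPM. Nuclear respiratory chain genes fell in 19 of 31 cases with none higher (22 adjusted over the list alone), at a median of -0.38 (camera adjusted p = 9.9e-07, adjusted p = 0.32 with an estimated correlation). ATP5F1C fell from 288 ± 46.8 to 190 ± 3.47 CPM. The members that fell numbered 11 without ADR_DMSO replicate 2 (median -0.25) and 10 without ADR_vinigrol replicate 1 (median -0.31).

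The other 15 lists in ADR had camera adjusted p-values from 0.056 to 0.86. Higher and lower members numbered 2 and 3 of 19 for heat shock, 3 and 5 of 23 for NRF2, 4 and 1 of 7 for metallothioneins, 4 and 3 of 23 for lysosome and 9 and 4 of 20 for p53 targets. Such counts were 1 and 5 of 14 for fatty acid synthesis and 3 and 7 of 20 for interferon response. They were 5 and 2 of 16 for hypoxia, 2 and 4 of 16 for glycolysis, 2 and 5 of 13 for mitochondrial mRNAs, 6 and 7 of 23 for calcium handling, 3 and 3 of 7 for AHR targets and 3 and 0 of 19 for luminal and epithelial markers. Immune cell markers had 0 and 0 of 6, and fibroblast and endothelial markers 0 and 3 of 6. The median and mean of the interferon list were 0.09 and -0.23, and those of lysosome also differed in sign. Adjusted over the list alone, the counts became 9 and 5 for p53 targets, 1 and 7 for fatty acid synthesis, 2 and 6 for mitochondrial mRNAs and 1 and 3 for fibroblast and endothelial markers, with the other counts the same. Adjusted over all genes, the counts without ADR_DMSO replicate 1 were 2 and 11 for heat shock, 5 and 10 for NRF2, 2 and 7 for glycolysis and 3 and 8 for mitochondrial mRNAs. Leaving out ADR_DMSO replicate 2 gave 5 and 1 for heat shock, 3 and 2 for NRF2, 3 and 3 for interferon response and 5 and 4 for glycolysis. NRF2 had 3 and 2 and interferon response 3 and 3 without ADR_vinigrol replicate 1, and calcium handling 6 and 4 without ADR_vinigrol replicate 2. The median of AHR targets was -0.20, also with CYP1A2, at 0 counts with vinigrol, set to its bound. Within the interferon list IFIT1 fell from 6.64 ± 1.49 to 1.59 ± 0.00421 CPM, while IRF1 rose from 14.2 ± 0.996 to 37.4 ± 3.27 CPM. MT2A, a metallothionein gene with near copies, rose from 979 ± 198 to 2490 ± 256 CPM.

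In T47D most tested members of the NF-kB, immediate early and MAPK feedback, interferon response, ATF4 and ER chaperone lists rose, and 13 of 20 estrogen response genes fell. Of the 16 lists called in T47D, 0 kept their call with an estimated correlation. LIF (ENSG00000128342, chromosome 22, 30240453 to 30246759) went from 1.01 ± 0.46 to 545 ± 10.3 CPM, a 548-fold rise (log2 9.10 ± 0.17, adjusted p = 1.1e-22). CDKN1A rose 34.3-fold to 888 ± 9.77 CPM and HSPA5 4.32-fold to 3520 ± 30.3 CPM. The progesterone receptor gene PGR fell from 684 ± 30 to 71.5 ± 4.98 CPM (log2 -3.26 ± 0.11, adjusted p = 5.9e-18).

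A total of 10290 of 18145 genes were called in T47D (5032 higher, 5258 lower), more than in 231 or ADR in the same fit, and 4797 of them differed at least 2-fold (1906 higher, 2891 lower). With library totals alone 3301 were higher and 7118 lower, and the median of all genes moved from -0.01 to -0.28. Among the largest rises, KRT6B, PTGS2 and TNFSF14 had 0 counts in both DMSO libraries. They reached 56.2 ± 2.69, 45.3 ± 1.71 and 11.7 ± 1.18 CPM, at least 303-fold, 244-fold and 63.1-fold higher. KLHDC7B rose to 214 ± 19.5 CPM from 0.186 ± 0.0206 and the acute phase gene SAA2 to 79.2 ± 1.59 CPM from 0.124 ± 0.0137. The chemokine gene CCL20 had 1 count over the DMSO libraries and 594 with vinigrol, a ratio of 689 with an exact 95% counting interval of 123 to 27300. KRT75 had 3 counts against 1008, a ratio of 390 with an interval of 133 to 1890. KRT6B, KRT75 and SAA2 have near copies with which they may share reads. The largest falls were those of CYP1A2 (72.2-fold), RBBP8NL (50.8-fold), TMEM52B (50.4-fold), the kinase gene MAP2K6 (42.8-fold), TRIL (31.8-fold), KLHDC7A (29.8-fold), ANKRD34A (25.6-fold) and GASK1A (24-fold). CYP1A2 fell from 23.8 ± 2.37 to 0.315 ± 0.121 CPM.

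NF-kB and inflammatory genes rose in 17 of 22 cases with none lower in T47D (18 adjusted over the list alone), at a median of 4.01 (camera adjusted p = 4.2e-14, adjusted p = 0.073 with an estimated correlation). With CXCL3, at 0 counts under DMSO, set to its bound the median was 3.78. ICAM1 rose from 5.78 ± 1.19 to 717 ± 2.71 CPM and TNFAIP2 from 42.2 ± 3.76 to 1550 ± 87.9 CPM. Immediate early and MAPK feedback genes rose in 24 of 26 cases with none lower (24 adjusted over the list alone), at a median of 2.80 (camera adjusted p = 6.8e-18, adjusted p = 0.073 with an estimated correlation). The median was 2.72 with EGR2 set to its bound. SPRY4, a feedback inhibitor of MAPK signalling, rose from 1.19 ± 0.261 to 159 ± 6.12 CPM. Interferon response genes rose in 17 of 20 cases and fell in 1 (18 and 1 adjusted over the list alone), at a median of 2.29 (camera adjusted p = 4.7e-09, adjusted p = 0.092 with an estimated correlation). IRF1 rose from 4.43 ± 0.0322 to 143 ± 9.59 CPM, OAS3 from 106 ± 2.24 to 408 ± 32.3 CPM and MX1 from 15.4 ± 2.09 to 90.9 ± 11.5 CPM.

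ATF4 list members rose in 36 of 42 cases and fell in 3 in T47D (36 and 4 adjusted over the list alone), at a median of 1.05 (camera adjusted p = 5e-14, adjusted p = 0.084 with an estimated correlation). ATF3 rose 13.5-fold and GDF15 from 2.8 ± 0.648 to 366 ± 5.53 CPM. ER chaperones and ERAD genes rose in 36 of 38 cases with none lower (37 adjusted over the list alone), at a median of 0.84 (camera adjusted p = 4.1e-14, adjusted p = 0.073 with an estimated correlation). Heat shock genes rose in 16 of 19 cases and fell in 1 (the same adjusted over the list alone), at a median of 0.76 (camera adjusted p = 2.4e-05, adjusted p = 0.27 with an estimated correlation). HSPB1 rose from 855 ± 192 to 2230 ± 111 CPM. NRF2 genes rose in 15 of 23 cases and fell in 1 (15 and 2 adjusted over the list alone), at a median of 0.68 (camera adjusted p = 0.00035, adjusted p = 0.14 with an estimated correlation). HMOX1 rose 7.33-fold. Autophagy genes rose in 15 of 27 cases and fell in 1 (the same adjusted over the list alone), at a median of 0.42 (camera adjusted p = 0.00035, adjusted p = 0.1 with an estimated correlation). MAP1LC3B rose from 77.7 ± 1.89 to 263 ± 1.87 CPM. Lysosome genes rose in 15 of 23 cases and fell in 1 (the same adjusted over the list alone), at a median of 0.42 (camera adjusted p = 0.0011, adjusted p = 0.084 with an estimated correlation). The cholesterol transporter gene NPC1 rose from 43.8 ± 2.03 to 148 ± 3.01 CPM.

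Pro-apoptotic genes rose in 8 of 13 cases and fell in 3 in T47D (the same adjusted over the list alone), at a median of 0.99 (camera adjusted p = 0.0015, adjusted p = 0.073 with an estimated correlation). BBC3 rose from 1.82 ± 1.2 to 66.5 ± 1.01 CPM and TNFRSF10B 7.61-fold. Cholesterol synthesis genes rose in 17 of 25 cases and fell in 5 (the same adjusted over the list alone), at a median of 0.58 (camera adjusted p = 0.00022, adjusted p = 0.073 with an estimated correlation). HMGCS1 rose 5.08-fold and LDLR, the low density lipoprotein receptor gene, 4.33-fold. Luminal and epithelial markers rose in 12 of 19 cases and fell in 5 (14 and 5 adjusted over the list alone), at a median of 0.32 (camera adjusted p = 0.0066, adjusted p = 0.1 with an estimated correlation). The tight junction gene CLDN4 rose from 182 ± 8.6 to 1430 ± 122 CPM. Estrogen response genes fell in 13 of 20 cases and rose in 3 (the same adjusted over the list alone), at a median of -0.56 (camera adjusted p = 0.007, adjusted p = 0.09 with an estimated correlation). CXCL12 fell from 394 ± 7.02 to 43.6 ± 1.82 CPM, MYB from 42.4 ± 2.58 to 7.14 ± 0.77 CPM and ESR1 1.45-fold to 240 ± 2.49 CPM.

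G1/S genes fell in 21 of 27 cases and rose in 2 in T47D (the same adjusted over the list alone), at a median of -0.81 (camera adjusted p = 1.4e-06, adjusted p = 0.09 with an estimated correlation). MCM3 fell 3.16-fold and PCNA from 173 ± 4.83 to 68.2 ± 3.35 CPM. G2/M genes fell in 15 of 26 cases and rose in 1 (the same adjusted over the list alone), at a median of -0.39 (camera adjusted p = 0.002, adjusted p = 0.33 with an estimated correlation). The checkpoint gene BUB1B fell from 78.9 ± 5.81 to 39.6 ± 1.27 CPM. Mitochondrial mRNAs fell in 7 of 13 cases with none higher (7 adjusted over the list alone), at a median of -0.45 (camera adjusted p = 0.032, adjusted p = 0.41 with an estimated correlation). That call was lost without T47D_DMSO replicate 1 (adjusted p = 0.059) and without T47D_vinigrol replicate 2 (adjusted p = 0.063).

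The remaining 12 lists in T47D had camera adjusted p-values from 0.052 to 0.92. Higher and lower members numbered 1 and 1 of 7 for metallothioneins, 5 and 1 of 8 for anti-apoptotic genes, 9 and 8 of 20 for p53 targets, 7 and 2 of 14 for fatty acid synthesis, 7 and 3 of 16 for hypoxia and 8 and 2 of 16 for glycolysis. They were 2 and 7 of 31 for the nuclear respiratory chain, 12 and 7 of 23 for calcium handling, 3 and 2 of 7 for AHR targets, 6 and 1 of 16 for mesenchymal and basal markers, 0 and 2 of 6 for immune cell markers and 1 and 0 of 6 for fibroblast and endothelial markers. The median of p53 targets was -0.24 and their mean 0.53, AHR targets had a median of 0.33 and a mean of -0.35, and immune cell markers had a median of 0.74 with a camera direction of down. Adjusted over the list alone, the counts became 7 and 4 for hypoxia, 2 and 4 for the nuclear respiratory chain and 12 and 9 for calcium handling, with the other counts the same. Adjusted over all genes, leaving out T47D_DMSO replicate 2 gave 3 and 2 for fatty acid synthesis, 4 and 4 for hypoxia and 1 and 3 for the nuclear respiratory chain. That chain had 1 and 11 without T47D_DMSO replicate 1 and 1 and 4 without T47D_vinigrol replicate 2, calcium handling 6 and 7 without T47D_vinigrol replicate 2 and hypoxia 4 and 3 without T47D_vinigrol replicate 1. The median of mesenchymal and basal markers was 1.31, also with ZEB2, at 0 counts with vinigrol, set to its bound. BIRC3 of the anti-apoptotic list rose from 7.63 ± 1.16 to 280 ± 10.6 CPM, and the voltage-gated calcium channel gene CACNA1D fell from 58.7 ± 1.92 to 12.5 ± 1.16 CPM.

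**Figure D2:**
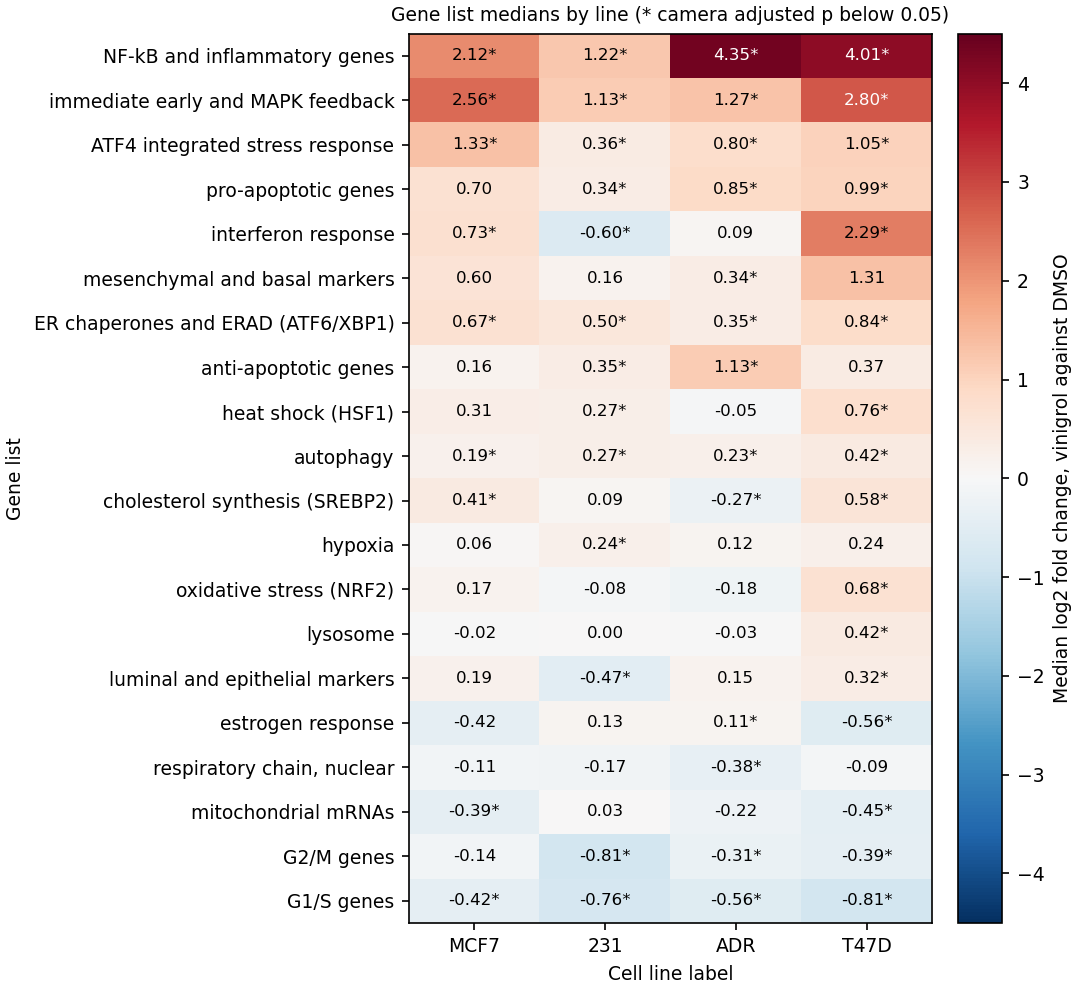
Median log2 fold change, vinigrol against DMSO, of each gene list (rows) in each cell line (columns), on a colour scale from blue (lower) to red (higher), with * for a camera adjusted p below 0.05. The 20 lists called in at least 1 line at the preset correlation are shown. With an estimated correlation 0 calls were left in MCF7, 3 in 231, 6 in ADR and 0 in T47D. NF-kB and inflammatory genes had medians of 2.12, 1.22, 4.35 and 4.01 in MCF7, 231, ADR and T47D, and G1/S genes had negative medians in all 4.

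The next comparison asked what the 4 lines had in common. The mean of the 4 within-line effects passed the test for 7850 of 18657 genes (3717 higher, 4133 lower), 1533 of them at least 2-fold, while library totals alone gave 2749 higher and 5328 lower. Genes called in the same direction in all 4 lines included LIF, AREG and CDKN1A among the higher ones, and SKP2, MCM3 and DDB2 among the lower ones. LIF rose by a mean log2 of 4.97 ± 0.09 (adjusted p = 1.4e-26), from 3.11-fold in 231 to 548-fold in T47D. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339) rose by a mean of 3.23 ± 0.07, from 3.21-fold in 231 to 34.3-fold in T47D. SKP2, a subunit of the ubiquitin ligase that targets p27 (ENSG00000145604, chromosome 5, 36151989 to 36184319), had a mean log2 change of -1.53 ± 0.07 (adjusted p = 3.5e-17) and fell 2.44-fold in MCF7, 2.42-fold in 231, 2.86-fold in ADR and 3.92-fold in T47D.

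The other genes with the smallest adjusted p among those higher in all 4 lines were RELB (mean log2 3.53), JUNB (2.87), ERRFI1, an EGF receptor inhibitor (3.44), AREG (3.77), DUSP6 (3.10), PPP1R15A, a phosphatase subunit that reverses eIF2alpha phosphorylation (2.44), the urokinase receptor gene PLAUR (3.12) and the integrin gene ITGA2 (2.56). Each had an SE of at most 0.09. Those lower in all 4 lines were the small GTPase gene RHOB (-1.41), DDB2 (-1.58), the helicase gene BRIP1 (-1.29), UNG (-1.14), ZMYM3 (-1.34), B4GAT1 (-1.37), SUOX (-1.32), the replicative helicase gene MCM3 (-1.04) and the replication kinase gene CDC7 (-1.42), with SEs of at most 0.08. RHOB fell 7.73-fold in MCF7 and 1.25-fold in 231. The RHOB call in 231 was lost without 231_DMSO replicate 2 (adjusted p = 0.2), 231_vinigrol replicate 1 (0.13) or 231_vinigrol replicate 2 (0.1). That of MCM3 in MCF7 was lost without MCF7_DMSO replicate 1 (adjusted p = 0.095) or MCF7_vinigrol replicate 1 (0.09). Among the genes set in advance, ATF4 rose in each line, by 3.04-fold in MCF7, 1.27-fold in 231, 2.04-fold in ADR and 2.11-fold in T47D. DDIT3, the gene of the stress factor CHOP, rose 9.72-fold, 1.68-fold, 2.15-fold and 8.48-fold in the same order. The cyclin D1 gene CCND1 rose 1.68-fold, 1.55-fold, 1.19-fold and 2.80-fold. Its call in ADR was lost without ADR_vinigrol replicate 1 (adjusted p = 0.087) or replicate 2 (0.14) and with ADR fitted alone (0.14), and its call in MCF7 without MCF7_DMSO replicate 1 (0.075). FOS rose 16.7-fold, 3.34-fold, 1.62-fold and 29.5-fold, and its call in ADR was lost without ADR_vinigrol replicate 2 (adjusted p = 0.054). MYC was 1.41-fold higher in MCF7 without passing the test (adjusted p = 0.12).

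**Figure D3:**
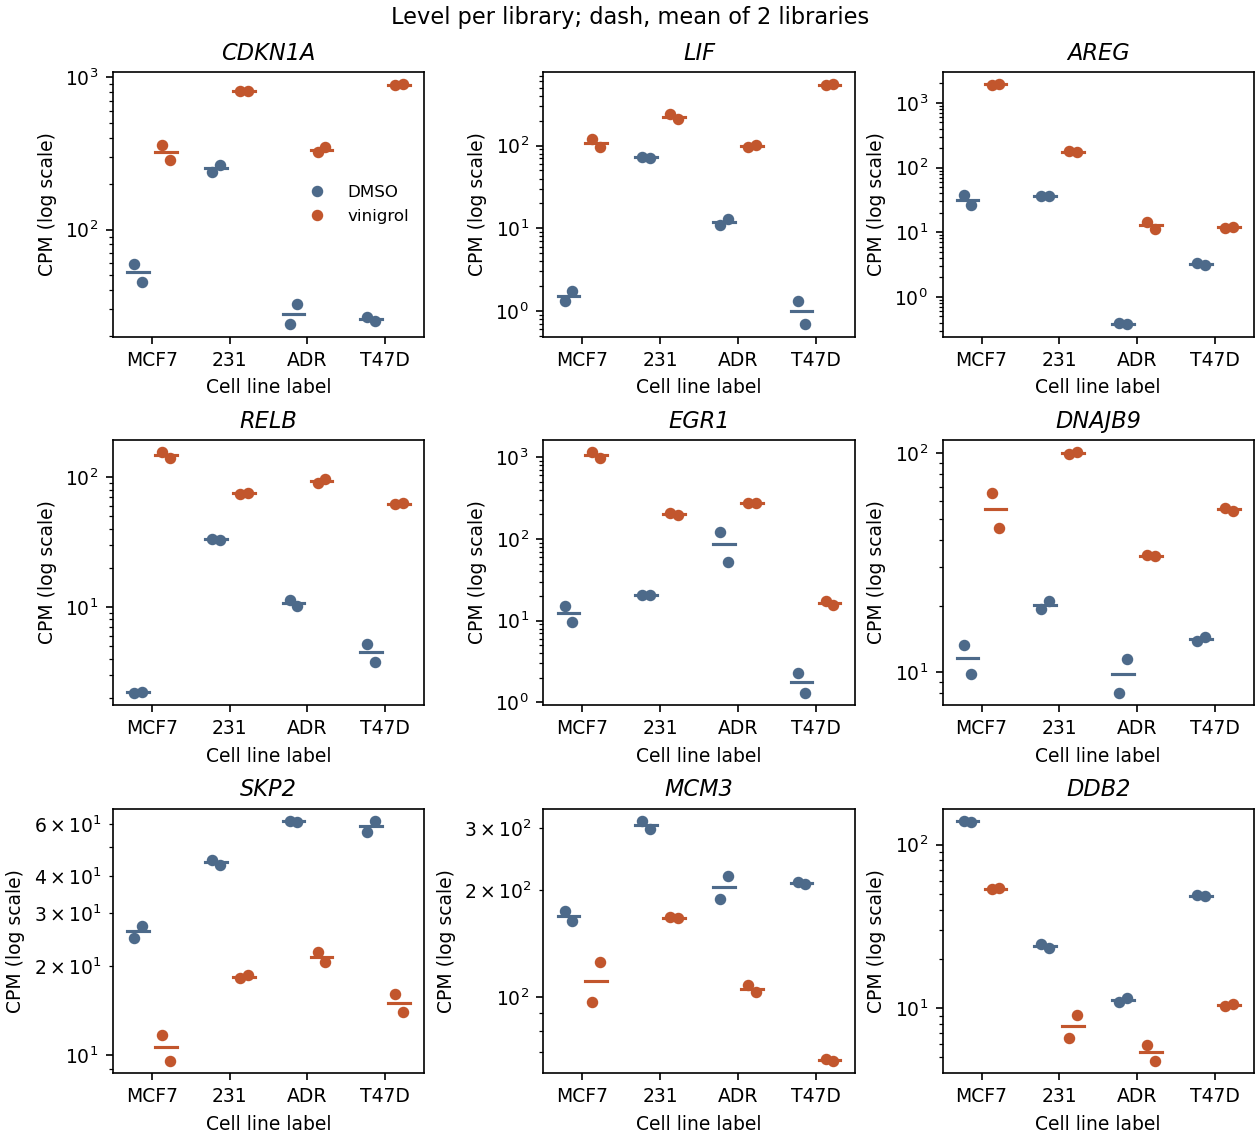
Level of 9 genes in each library, as TMM-scaled CPM on a log axis, by cell line, with DMSO libraries in blue and vinigrol libraries in orange and a dash at the mean of 2 libraries. In each line both vinigrol libraries lie above both DMSO libraries for CDKN1A, LIF, AREG, RELB, EGR1 and DNAJB9, and below them for SKP2, MCM3 and DDB2.

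Of 11597 genes tested in all lines, 413 were higher in all 4 and 155 lower in all 4, against 17.8 and 11.1 for independent lists of the same sizes. At least 2-fold changes were shared by 64 higher and 11 lower genes, against 0.0856 and 0.0474. Every pair of lines shared more calls than independent lists would, in both directions. MCF7 and T47D shared 1036 higher genes against 492.6 expected (odds ratio 6.86, two-sided Fisher's exact test, adjusted p = 2.3e-222 over 12 tests), and MCF7 and ADR shared the fewest lower genes, 286 against 195.5 (odds ratio 1.75, adjusted p = 4.29e-13). Opposite calls between lines were seen for 1164 genes, with no expected count made. Across genes, which are not independent replicates, the fold changes of 2 lines had Pearson correlations from 0.31 (MCF7 and 231) to 0.51 (MCF7 and T47D). Of the 28 lists, 5 were higher in all 4 lines (ATF4, ER chaperones and ERAD, autophagy, immediate early and MAPK feedback, NF-kB) and 1 was lower in all 4 (G1/S genes). None of these 6 kept its call in all 4 lines, as the calls were lost in MCF7 (adjusted p = 0.24 to 0.66 with an estimated correlation) and in T47D (adjusted p = 0.073 to 0.1).

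The last comparisons asked where the effect of vinigrol differed between lines. NF-kB and inflammatory genes rose less in 231 than in ADR, with a median difference of -3.48 (adjusted p = 0.006 with an estimated correlation). NFKBIA, the NF-kB inhibitor gene (ENSG00000100906, chromosome 14, 35401511 to 35404749), rose in ADR by 3.62 on the log2 scale and had an effect of -0.18 in 231 that did not pass the test, a difference of -3.79 ± 0.14 (adjusted p = 7.1e-16). The difference of 231 minus ADR was -4.45 ± 0.13 for the laminin gene LAMB3, -7.46 ± 0.24 for CXCL1 and -4.23 ± 0.16 for TNFAIP3. In total, 2494 genes differed between 231 and ADR (1007 higher in 231 minus ADR, 1487 lower), or 675 and 1635 with library totals alone. Leaving out any 1 of the 4 libraries of 231 gave 1570 to 1633 genes, and leaving out ADR_DMSO replicate 1 gave 4390.

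Between 231 and T47D 5503 genes differed (2286 higher and 3217 lower in 231 minus T47D, or 3060 and 2256 with library totals alone). SAT1, a polyamine-degrading enzyme gene, rose by 4.66 in T47D and fell by 0.33 in 231, a difference of -4.99 ± 0.14 (adjusted p = 8.5e-19). The differences were -5.09 ± 0.14 for TNFAIP2, -7.46 ± 0.21 for LIF and -9.90 ± 0.29 for SAA2. Between ADR and T47D 6213 genes differed (2695 higher and 3518 lower in ADR minus T47D, or 3851 and 2024 with library totals alone). AFF3, a nuclear factor gene (ENSG00000144218, chromosome 2, 99545419 to 100192428), rose by 2.25 in ADR and fell by 3.35 in T47D on the log2 scale, a difference of 5.60 ± 0.17 (adjusted p = 6.5e-18). GPRC5A, RAB11FIP1 and ANXA1, the annexin A1 gene, fell in ADR and rose in T47D, with differences of -5.22 ± 0.13, -4.24 ± 0.15 and -5.32 ± 0.19.

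MCF7 differed from the mean of the other 3 lines in 2233 genes (1012 higher, 1221 lower, or 1340 and 838 with library totals alone). LMO7, a cell junction protein gene (ENSG00000136153, chromosome 13, 75620434 to 75859870), rose by 4.05 in MCF7, against -0.34, -1.28 and -0.05 in 231, ADR and T47D, a difference of 4.61 ± 0.17 (adjusted p = 1.9e-17). The death receptor gene TNFRSF21 (5.38 ± 0.22) and TM4SF1 (4.32 ± 0.21) also rose more in MCF7. SOD2, the mitochondrial superoxide dismutase gene, had effects of -0.13 in MCF7, 1.65 in 231, 4.01 in ADR and 4.17 in T47D, a difference of -3.41 ± 0.16 (adjusted p = 1.3e-15). The MCF7 libraries were made with another library kit and aligner, so line and method cannot be told apart in this comparison.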

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

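The tests of list differences between lines, of the size of the T47D response, of carry-over between libraries, of interferon scaling and of random lists were chosen after the results were seen, while the count of other splits, the test of interferon members by level and the NF-kB correlation were written down before their results were seen.

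The effect of vinigrol differed between lines by the interaction test, which brought these results out. The number of genes that differed was 2494 for 231 minus ADR, 5503 for 231 minus T47D, 6213 for ADR minus T47D and 2233 for MCF7 minus the mean of the other 3 lines. For 231 minus ADR the log2 differences of the named genes were -4.45 for LAMB3, -7.46 for CXCL1, -3.79 for NFKBIA and -4.23 for TNFAIP3. For 231 minus T47D they were -5.09 for TNFAIP2, -4.99 for SAT1, -7.46 for LIF and -9.90 for SAA2. For ADR minus T47D they were -5.22 for GPRC5A, 5.60 for AFF3, -4.24 for RAB11FIP1 and -5.32 for ANXA1. For MCF7 minus the others they were 4.61 for LMO7, 5.38 for TNFRSF21, -3.41 for SOD2 and 4.32 for TM4SF1.

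Gene lists also differed between lines at the preset correlation, in 12 of 28 cases for 231 minus ADR, 15 for 231 minus T47D, 14 for ADR minus T47D and 9 for MCF7 minus the others. With an estimated correlation these counts were 1, 0, 1 and 0, the lists being NF-kB for 231 minus ADR (adjusted p = 0.006) and cholesterol synthesis for ADR minus T47D (adjusted p = 0.04). The median differences of 231 minus ADR were -0.66 for the ATF4 list, 0.31 for heat shock, -0.39 for pro-apoptotic and -0.65 for anti-apoptotic genes, -0.51 for G2/M genes, 0.22 for cholesterol synthesis and -0.53 for immediate early and MAPK feedback. They were -3.48 for NF-kB, -0.30 for interferon response, 0.21 for the nuclear respiratory chain, 0.30 for mitochondrial mRNAs and -0.32 for mesenchymal and basal markers.

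The median differences of 231 minus T47D were -0.74 for the ATF4 list, -0.49 for ER chaperones and ERAD, -0.70 for NRF2, -0.40 for lysosome, -1.10 for pro-apoptotic genes, -0.40 for G2/M genes, -0.68 for cholesterol and -0.28 for fatty acid synthesis. They were 0.52 for estrogen response, -1.53 for immediate early and MAPK feedback, -3.60 for NF-kB, -2.80 for interferon response, 0.37 for mitochondrial mRNAs, -1.02 for AHR targets and -0.89 for luminal and epithelial markers.

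The median differences of ADR minus T47D were -0.49 for ER chaperones and ERAD, -0.82 for heat shock, -0.71 for NRF2, -0.27 for autophagy, -0.43 for lysosome, 0.66 for anti-apoptotic genes, -0.88 for cholesterol and -0.41 for fatty acid synthesis. They were 0.70 for estrogen response, -1.16 for immediate early and MAPK feedback, -2.06 for interferon response, -0.65 for glycolysis, -0.33 for the nuclear respiratory chain and -0.78 for AHR targets. Those of MCF7 minus the others were 0.54 for the ATF4 list, -0.25 for pro-apoptotic and -0.66 for anti-apoptotic genes, 0.17 for G1/S and 0.29 for G2/M genes, 0.30 for cholesterol synthesis, 1.35 for immediate early and MAPK feedback, -1.79 for NF-kB and -0.29 for mitochondrial mRNAs. In the MCF7 comparison line cannot be separated from library kit and aligner.

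The first pattern is the size of the T47D response, with 4797 genes called at least 2-fold against 1311 in 231 and 1388 in ADR. Depth was argued against, since with all 12 libraries thinned to the smallest total (12218619 counts) T47D still had 4606 such genes, 3.39 times the higher of the other lines. Scaling was argued against by a fit without mitochondrial genes and on library totals (5673 genes, 3.94 times), and the shared spread by fitting each line alone (4559 genes, 3.49 times). What remains open is a difference between the lines themselves, or between their cultures at the time of treatment, which the labels do not separate and which was not tested.

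The second pattern is the interferon list, lower in 231 and higher in T47D (median difference -2.80, adjusted p = 0.06 with an estimated correlation). Scaling was argued against, since the median nearest to 0 over both lines with RLE factors or library totals was -0.59, in 231, and no median changed sign. Of the 11 members with at least 10 CPM in the higher group of each line, 9 (81.8%) went down in 231 and up in T47D. Of these, 6 were called in both. Low counts in the lower group and a difference between the lines stay open. With the estimated correlation the list difference itself fell short of the threshold.

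The third pattern is the smaller rise of NF-kB genes in 231 than in ADR. In DMSO replicate 1, 21 of the 22 genes were higher in 231 (median 2.14 in log2 of CPM plus 1). Over both vinigrol libraries 5 were (-0.66). Across these genes, which are not independent replicates, the DMSO difference was set against that of the fold change over DMSO replicate 2. Spearman's rho was -0.52 and Pearson's r -0.55 (permutation test, 100000 permutations, two-sided p = 0.015 for rho). Of 10000 random lists 4.6% had a rho as low (median -0.15). DMSO enters the fold change with a minus sign, so a negative rho is built in. A higher level before treatment may leave less room for a rise. However, 17 of the 22 genes ended lower in 231 than in ADR, which that account alone does not give.

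Genes called lower in 231 from a DMSO level under 2 CPM numbered 278, and 1.1% of them had a DMSO excess within 2 times that predicted from ADR and T47D transcripts in the same libraries. Among the 9 of them with an ADR level at least 100 times higher it was 33.3%. The median share of ADR-specific transcripts was 0.151% in 231_DMSO replicate 1 and 0 in replicate 2 (upper quartiles 0.276% and 0.105%). ABCB1, above 2 CPM in 231 with DMSO, was outside this test. ADR transcripts may account for some or all of that level, and so of its call, which stays open.

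For the mean effect over the 4 lines, 60 of 648 splits of the libraries within lines were drawn. Only the real one gave as many as 7850 genes, which does not exclude chance differences between cultures. The highest other split gave 4890 and had 2 libraries moved.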

How the results depend on the processing

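The fits limited to a mean of at least 1 CPM or without mitochondrial genes and the counts of list and family members with a library left out were chosen after seeing the data, and all other alternatives were planned.

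No called list and no named gene that passed the test changed direction under an alternative run for it. With library totals alone, which lower the median of all genes, calls went from mostly higher to mostly lower in MCF7 (1195 higher, 1413 lower) and from mostly lower to mostly higher for 231 minus T47D (3060 and 2256), ADR minus T47D (3851 and 2024) and MCF7 minus the others (1340 and 838). Where higher and lower calls were close in number, other alternatives turned the balance to mostly higher too. In ADR these were RLE factors (2940 and 2796), DESeq2, voom, no count filter, at least 1 CPM in 2 libraries, the replicate block, ADR fitted alone, no mitochondrial genes (3126 and 2509), a 2-fold threshold and leaving out ADR_DMSO replicate 2 or either vinigrol library. In 231 they were DESeq2, 231 fitted alone and leaving out 231_vinigrol replicate 1, ADR_DMSO replicate 2 or any library of T47D. In T47D a mean of at least 1 CPM did so (4812 and 4592), for ADR minus T47D a 2-fold threshold and at least 1 CPM in 2 libraries (3082 and 2955), and for MCF7 minus the others a 2-fold threshold (506 and 491). With library totals 6 medians of uncalled lists turned, in T47D glycolysis (0.22 to -0.04) and in MCF7 hypoxia (0.06 to -0.04). In 231 these were cholesterol synthesis (0.09 to -0.01), calcium handling (0.03 to -0.07), metallothioneins (0.10 to -0.01) and mitochondrial mRNAs (0.03 to -0.08). Others turned with a library left out. Of the counts of called genes and lists, 88 stayed within 1.5 times the count reported and 17 did not, besides single libraries left out. A 2-fold threshold, which by construction counts fewer genes, left 1391 in MCF7, 1311 in 231, 1388 in ADR, 4797 in T47D, 1533 for the mean effect, 886 for 231 minus ADR, 2641 for 231 minus T47D, 2756 for ADR minus T47D, 997 for MCF7 minus the others and 75 genes shared by all 4 lines in place of 568. The estimated correlation left 0 lists in MCF7, 3 in 231, 6 in ADR and 0 in T47D. Fry, which tests each list by itself, called 1, 19, 20 and 24 in the same order, within 1.5 times in 231 and T47D. Per list, calls were the same in 364 cases, lost in 52 and gained in 24, and named genes kept theirs in 5508 cases, lost it in 40 and gained it in 61. The cause was not tested.

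The labels do not say that a replicate number marks a shared culture or day, so the numbers were not taken to pair libraries. The deviations of same-numbered libraries correlated at 0.255 in MCF7, 0.005 in 231, 0.012 in ADR and -0.032 in T47D, and with 2 numbers per line this leaves a pairing in MCF7 open. The fit with a replicate block called 4223 genes in MCF7, including all 2456 called without it, and moved no other count of calls by over 1.5 times. With the block the interferon call in MCF7 (adjusted p = 0.083) and the pro-apoptotic call in 231 (adjusted p = 0.068) were lost. Heat shock (adjusted p = 0.042) and NRF2 (adjusted p = 0.027) in MCF7 and the nuclear respiratory chain in 231 (adjusted p = 0.033) were gained. CCND1 in ADR was at an adjusted p of 0.054 and MYC in MCF7 at 0.03.

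With each library left out in turn, the lone library was assumed to vary like the other groups. Counts ran from 1594 (without MCF7_DMSO replicate 1) to 2787 in MCF7, from 3589 (without 231_vinigrol replicate 2) to 6765 in 231, from 4029 to 6653 in ADR, from 8736 to 11229 in T47D and from 7263 to 7895 for the mean effect. They ran from 1570 to 4390 for 231 minus ADR, 4332 to 6602 for 231 minus T47D, 4923 to 7150 for ADR minus T47D and 1634 to 2613 for MCF7 minus the others. Lists called ran from 8 to 10 in MCF7, 12 to 13 in 231, 13 to 15 in ADR and 15 to 17 in T47D. List calls were gained for NRF2 in MCF7 without MCF7_DMSO replicate 2 (adjusted p = 0.0027) or MCF7_vinigrol replicate 1 (0.00095), and without the latter for heat shock (0.0094) and AHR targets (0.02). In ADR they were gained for heat shock without ADR_DMSO replicate 1 (adjusted p = 0.011), and for fatty acid synthesis (0.041), hypoxia (0.031) and metallothioneins (0.013) without ADR_DMSO replicate 2. In T47D they were gained for anti-apoptotic genes without T47D_DMSO replicate 2 (adjusted p = 0.048), and for anti-apoptotic genes (0.031) and mesenchymal and basal markers (0.018) without T47D_vinigrol replicate 2. Named genes kept their call in 6462 cases, lost it in 105 and gained it in 41. Log2 changes that kept their call and moved by over 1.5-fold included DUSP4 (6.42) and HMOX1 (3.36) in MCF7 without MCF7_DMSO replicate 2, BBC3 in T47D without T47D_DMSO replicate 1 (6.04) or replicate 2 (4.58), FOS in T47D without T47D_DMSO replicate 1 (5.51) and ESM1 (6.42 and 7.80) and G0S2 (6.16 and 7.52) in ADR without ADR_DMSO replicate 1 and 2. MAP2K6 in T47D was at -4.58 without T47D_vinigrol replicate 2 and at 0 counts in the vinigrol library left without replicate 1, and GASK1A was at -5.51 without T47D_vinigrol replicate 2. MCF7 had the lowest depth per library. The 6% of 1.5-fold changes called in simulated MCF7 data need not carry over, since far fewer genes were changed there.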

Other observations

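The gene families and classes below and their scalings were chosen after the data were seen, and changes are relative to TMM scaling unless library totals are named.

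No set test was run on these families. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, rose in 12 of 17 cases in MCF7 (median 0.89), 11 of 18 in 231 (0.33), 8 of 18 in ADR (0.13) and 15 of 18 in T47D (0.61), with 1 lower in 231 and in T47D, and the medians kept their sign with RLE factors and with library totals. With 1 library left out the count fell as low as 5 in 231 (without 231_vinigrol replicate 2), and in ADR it was 6 higher and 5 lower without ADR_DMSO replicate 1 (median 0.02) and 12 higher without ADR_DMSO replicate 2 (0.26). Several of them are members of the ATF4 list. Cytosolic ribosomal protein genes had 34 of 78 lower in ADR (median -0.29), which rested on ADR_DMSO replicate 2. Without that library 4 were lower and 3 higher (-0.02), and without ADR_DMSO replicate 1 73 were lower (-0.50). The count was 9 without ADR_vinigrol replicate 1 and 14 without ADR_vinigrol replicate 2. In T47D 53 of 78 were higher and 1 lower (median 0.34), against 23 to 29 with a library of T47D left out, and with library totals 9 were higher and 4 lower (0.07). In MCF7 0 were higher and 1 lower of 76, and in 231 1 and 1 of 78. Ribosomal protein genes have many pseudogenes with which they can share reads.

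Keratin genes had 15 higher and 1 lower of 20 in T47D (median 1.28, or 13 higher and 1.01 with library totals), 6 and 1 of 11 in MCF7 (1.36), 3 and 6 of 20 in 231 (0) and 1 and 3 of 20 in ADR (0.08). Integrin genes had 7 higher and 1 lower of 12 in MCF7 (median 1.49), 5 and 3 of 18 in 231 (0.11, or 4 and 5 with library totals), 9 and 2 of 18 in ADR (0.57) and 8 and 2 of 18 in T47D (0.65, or 7 and 5 with library totals). Long intergenic noncoding RNAs fell in 340 of 918 cases in T47D and rose in 51 (median -0.77, or -1.04 with library totals), against 41 lower and 20 higher of 358 in MCF7, 69 and 66 of 918 in 231 and 93 and 61 of 918 in ADR.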
